A study of Drosophila melanogaster with 3 samples.

How the data were processed

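ChIP-seq of GFP-tagged lz was analysed in 3 biological replicates of whole white prepupae, which, per the labels, were of mixed sex and are numbered 1 to 3. The labels list a separate biological material for each replicate, and the 3 replicate lists are not identical. Chromatin was sheared by sonication, per the labels. No control sample was analysed here; per the deposited file lists, peaks were called against 1 control alignment. The aligner, the peak caller and the level of reproducibility that set the threshold are not given in the sources used here.

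The authors deposited a list of 30000 peaks and background regions for each replicate, a list of 30000 called on the pooled replicates, and a set thresholded by the irreproducible discovery rate, on the dm6 and dm3 builds. The signal column is the authors' signal value per peak; its scale differs between lists, so it was used only to rank peaks within a list. The −log10 q-value column is as deposited by the authors, and it is at its upper cap for all 8048 thresholded dm6 peaks, so it cannot rank them. Another significance column held a single placeholder value and was not used. Where 2 summits share an interval (130 thresholded rows) each summit was kept. The thresholded dm6 set was checked to equal the 8048 highest pooled peaks by signal. Read depth is unknown, as the lists hold no counts, and the precision given is that of counts of peaks or genes.

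Analyses were run on dm6 with Ensembl gene models, whose chromosome names and lengths match, and the RefSeq genome sequence; the dm3 lists (7763 thresholded peaks) entered checks that need neither genes nor sequence. Coordinates are 1-based. Each replicate was cut to its 8048 highest peaks. Summits within 100 bp matched, with 100 circular shifts as a background. A summit was a promoter summit within 500 bp of any TSS and otherwise exonic, intronic or intergenic, and was compared with 1000 sets of uniform positions with the same number per chromosome. A gene had a peak when a summit lay in its span or 1 kb to either side. The 19 gene lists and 16 motifs were fixed before the data were examined; 3 list symbols were matched by another name and 0 were missing. Lists were compared with 10000 random lists with the same numbers of genes per decile of gene span, by a two-sided permutation test. Motifs were searched on both strands within 50 bp of the summit and in a window 500 bp away on a randomly chosen side, by the two-sided exact McNemar test. Benjamini-Hochberg adjustment was made over the lists and over the motifs. Peaks and genes are not independent replicates, so these p-values describe the peak set, and the replicate mean and SD stands beside them. Comparisons between peaks of different strength and between chromosomes had no test.

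The AT-rich summits seen in the data led to further comparisons chosen after seeing the data: positions on the same chromosome over 1 kb from any pooled peak with the same number of G and C (found for all 8048 windows), and up to 100 permutations of each consensus.

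Genes were named by a rule fixed before the data were examined: lz, all members of the reported lz targets and the crystal cell list, up to 4 members of each other list with the highest peaks, the first 2 by name without a peak where under 50 percent have one, and the gene with the TSS nearest to each of the 10 strongest peaks. Some genes that the rule names, with and without peaks, are covered by the counts only. Alternatives covered the matching distance, the number of peaks, the build, the promoter window, the motif window and flank, the gene span, the matching of lists, the 4024 strongest thresholded peaks, and leaving out each replicate (thresholded peaks matched in both others). Leaving out replicate 1, 2 or 3 kept 5793, 6094 and 5710 peaks. A peak can be lost there because a remaining replicate lacks it. The alternatives drew fewer random lists and uniform sets than the main tests, so their smallest possible p-values are larger. Tests were tried on simulated data first. Of 200 simulated lists of 30 genes drawn from 13968 with no difference, 3.5% were called at p 0.05. Of 200 with shares 30 points higher, 88.0% were called. These calls used unadjusted p-values and hits drawn independently for each gene. They do not cover smaller lists, such as the 13 reported lz targets, or lists of neighbouring genes. Of 50 simulated sets of 8048 peak windows with no difference, 2.0% were called, and with the Runx consensus planted in 2 percent of summit windows, 100% were called. Simulated summit and flank windows had the same base composition, unlike the real ones (33.7% against 44.1% G and C). The simulation therefore does not cover calls that come from base composition. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.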

Results

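Lozenge (lz) is a Runx-family transcription factor of the fruit fly with known roles in crystal cells (a blood cell type), in photoreceptor and cone cell specification and in olfactory sensilla. Its binding across the genome was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole *Drosophila melanogaster* of both sexes at the white prepupa stage, the onset of metamorphosis. The animals were transgenic, per the labels, and carried lz fused at its C-terminus to GFP. The fusion protein was precipitated through the GFP tag. The samples form 1 group of 3 biological replicates, with no second condition. Each replicate had a list of 30000 peaks and background regions, here termed calls, on the dm6 build. The pooled replicates had another list of 30000. The authors' thresholded set held 8048 peaks with a median width of 430 bp that together cover 2.84 Mb. Read depth is unknown, because the lists hold no read counts. A peak's signal is the authors' own value and was used here only to rank peaks within 1 list. The thresholded set equals the 8048 peaks of highest signal in the pooled list, so each replicate was represented by its own 8048 highest peaks.

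The first question was how well the replicates recovered the same sites. Of the 8048 highest peaks per replicate, 71.7% of summits in replicates 1 and 2, 77.1% in replicates 1 and 3, and 73.4% in replicates 2 and 3 lay within 100 bp of a summit of the other replicate, a mean of 74.1% ± 2.72 (SD, n = 3 pairs). Shifting 1 list along the chromosomes left at most 1.71% of summits matched in 100 shifts. Among thresholded peaks, 5230 (65.0%, 95% Wilson interval 63.9 to 66.0) were found in all 3 replicates, 1907 (23.7%) in 2 replicates, 844 (10.5%) in 1 replicate and 67 (0.833%) in none. Replicate 2 recovered 81.2% of the thresholded peaks, against 85.5% in replicate 1 and 86.1% in replicate 3. Peak ranks correlated between replicates with Spearman's rho of 0.813 to 0.837 across matched peaks, which are not independent replicates.

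Peaks lay mainly at promoters and in introns. Of the 8048 summits, 3431 (42.6%, interval 41.6 to 43.7) lay within 500 bp of a transcription start site (TSS), 3.15 times the 13.5% of uniformly placed positions on the same chromosomes. The share across replicates was 42.3% ± 4.46 (SD, n = 3), so the excess was larger than the replicate spread. Introns outside promoters held 38.5% of summits against 39.5% of uniform positions, a difference that did not pass a two-sided permutation test (p = 0.0739). Exons outside promoters held 2.32% against 19.7%, and intergenic DNA held 16.5% against 27.2%. The promoter, exon and intergenic differences each had a permutation p of 0.002, the smallest that 1000 uniform sets can give. Promoter summits sat upstream: the median was -100 bp from the nearest TSS, and 2755 of the 3431 (80.3%, interval 78.9 to 81.6) were upstream of it.

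**Figure D1:**
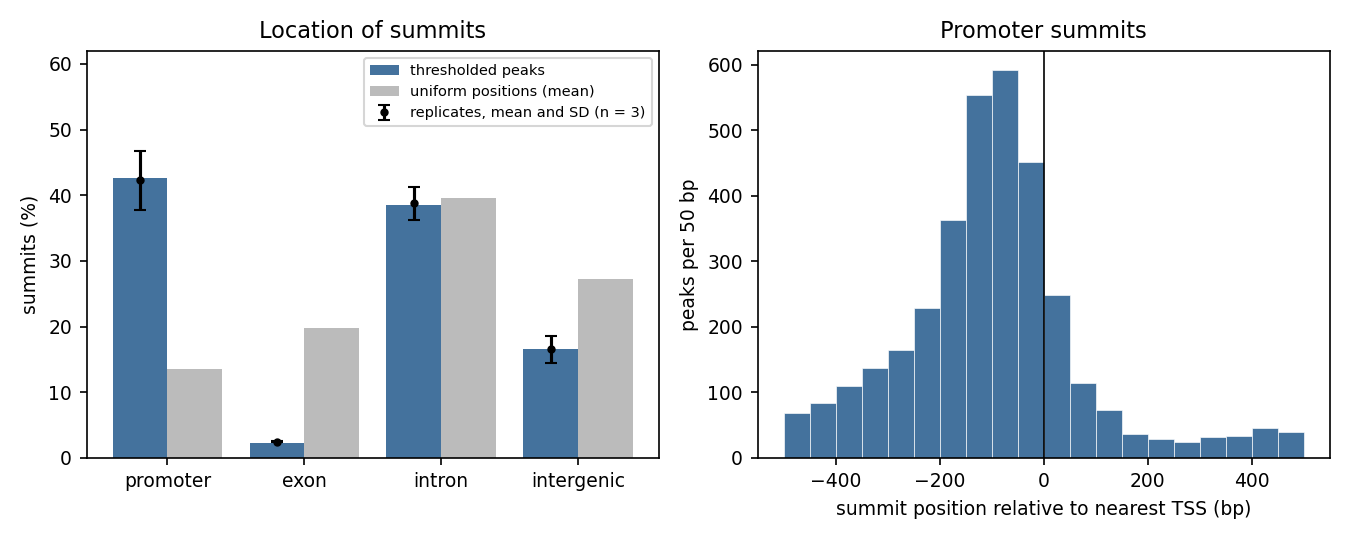
Left, percent of thresholded summits (blue) and of uniformly placed positions (grey) in each location class, with the mean and SD of the 3 replicates' highest peaks as points and bars. Right, number of promoter summits per 50 bp by distance to the nearest TSS in bp; 2755 of 3431 lie on the upstream (negative) side.

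Along the chromosomes, the X held 66.8 peaks per Mb, the large autosomal arms between 55.2 (2R) and 61.9 (2L), the small chromosome 4 had 20.0, and the Y had none. The ratio of X to autosomal density was 1.14, with 1.13 ± 0.0800 across replicates (SD, n = 3); it was not tested. The strongest peak of all (dm6, chromosome 3L, 19590385 to 19590841) had its summit 90 bp upstream of CG14100 (FBgn0036889) and ranked 1 in each replicate. The next strongest lay just upstream of the UDP-galactose transporter gene Ugalt and ranked 2 in each replicate. The third (chromosome 2L, 480574 to 481340) lay in an intron of ush, which encodes a cofactor of GATA factors, with cbt as the gene of the nearest TSS, and ranked 3 in each replicate. Among the 10 strongest peaks, those at PNPase, CG1888, Chro and Tcs5 were also within 500 bp of a TSS. The peaks whose nearest TSS was that of CG11050 or Lk6 were intronic, and the peak assigned to CG13323 in this way was intergenic, 11917 bp from the TSS.

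At lz itself (FBgn0002576, chromosome X, 9284649 to 9303636), the thresholded set held 3 peaks within the gene span or 1 kb of it. All 3 were intronic, with summits at 9295728, 9298290 and 9300109 and ranks of 5413, 3295 and 6926 among the 8048 peaks. The highest 8048 peaks of replicates 1, 2 and 3 held 3, 3 and 2 peaks at lz. The gene had 0.143 peaks per kb, more than 83.6% of the 1397 protein-coding genes in the same decile of gene span. The mean in that decile was 2.59 peaks per gene. The 4024 strongest peaks of the set included 1 of the 3 at lz. Transgenic flies may hold added copies of lz DNA, and the part of such copies in these peaks was not tested.

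Genes reported to respond to lz were compared with random lists of genes of matched span. Of 13 such genes, lz included, 7 had a peak (53.8%, against 56.6% in matched lists; adjusted permutation p = 1). The paired-domain gene sv (FBgn0005561, chromosome 4) had a peak of rank 522. Its summit at 1113345 lay past the end of sv at 1113317, so its 3' UTR annotation is that of another gene. The neural progenitor repressor gene dpn had 1 peak of rank 1165, and aos, a secreted Egfr inhibitor, had 5 with a top rank of 1040. Peaks at peb (rank 3103), klu (rank 6103) and pros (rank 7732) were weaker. No thresholded peak lay at PPO1 or PPO2, which encode the crystal cell prophenoloxidases, or at B-H1, B-H2, run or svp. The chromatin came from whole animals, so a missing peak does not show that binding was absent in a small group of cells. Of 13 crystal cell genes, 9 had a peak (69.2% against 58.9%, adjusted permutation p = 0.805). The ush gene held 20 peaks, 18, 16 and 22 in the 3 replicates, and sima, encoding a hypoxia-inducible factor, held 10. Ser had 4 peaks, the Notch receptor gene N had 3 with a top rank of 550, and sd and yki, of the Hippo pathway, had 2 each. The GATA factor gene srp and Mlf had none in the thresholded set, though replicate 1 alone had 1 at srp. When thresholded peaks were kept only if matched in both remaining replicates, klu had no peak without replicate 1 or 3, and pros had none whichever replicate was left out. The counts fell to 3 at aos and 5 at sima without replicate 1, and to 2 at Ser without replicate 1 or 3. At sd they were 0 without replicate 1 and 1 without replicate 2 or 3, and at yki 0 without replicate 2 and 1 without replicate 1 or 3.

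Over the other lists, 5328 of 13968 protein-coding genes (38.1%) had a peak, and 2 of the 19 lists were above and 4 below span-matched lists at an adjusted p of 0.05. Matching was on gene span and not on expression, so whether these calls separate active from silent genes was not tested. Genes of cytoplasmic ribosomal proteins stood out: 73 of 88 had a peak (83.0%, against 28.2% in matched lists; adjusted permutation p = 0.00127), with 81.4% ± 4.59 across replicates (SD, n = 3). Examples are RpS27, whose top peak of rank 152 lay 20 bp upstream of its TSS, RpL34b (rank 265) and RpL7 (rank 273). The top peak counted for RpL31 (rank 214) lay past the end of the gene, 1680 bp from its TSS. Notch pathway genes followed, with 13 of 17 (76.5% against 46.6%, adjusted permutation p = 0.0260; 76.5% ± 5.88 across replicates), among them mam with 12 peaks, fng and neur with 5 each, and E(spl)m3-HLH with 1 of rank 431. Without replicate 2 the Notch difference was 28.9 percentage points with an adjusted p of 0.0601, past the threshold no longer. The call was also lost with the gene span alone (15.1 points, adjusted permutation p = 0.467), with 5 kb added (24.4, adjusted p = 0.146) and in replicate 3 alone (23.9, adjusted p = 0.152). Leaving out replicate 1, 2 or 3 left 3, 1 and 1 peaks at fng, and leaving out replicate 3 left 3 at neur.

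Sensory receptor genes had few peaks. A peak was found at 2 of 59 odorant receptor genes (3.39% against 31.5%), Or85f and Or67c, and at 4 of 60 gustatory receptor genes (6.67% against 32.1%), Gr32a, Gr89a, Gr93a and Gr93b, each with an adjusted permutation p of 0.00127. The peak counted for Or85f also lies within 1 kb of RpL34b, as the genes are neighbours. Or67c had no peak whichever replicate was left out, which leaves 1 odorant receptor gene. The gustatory count was 1, Gr89a, without replicate 1 or 3, and 3 without replicate 2, where Gr93a had none. Both receptor lists stayed below matched lists in each case (adjusted permutation p = 0.00633). Fewer random lists were drawn there than in the main test, so this value and 0.00127 are not comparable. For cuticle protein genes it was 10 of 70 (14.3% against 28.6%, adjusted permutation p = 0.0175), and of 12 genes marking plasmatocytes, the main phagocytic blood cells, drpr alone had a peak (8.33% against 49.9%, adjusted p = 0.0175). The highest peaks of replicate 2 held none at drpr, so its peak was lost without replicate 1 or 3, which leaves 0 of 12. Leaving out replicate 2 gave the plasmatocyte list an adjusted p of 0.0601. Its difference from matched lists, -41.6 percentage points, was -20.3 with the gene span alone (adjusted permutation p = 0.467) and -9.41 with 5 kb added (adjusted p = 0.962), and its adjusted p ranged from 0.00475 to 0.962 over 11 alternatives. The cuticle list had 0.0538 without replicate 1 and 0.104 without replicate 3, and its call was also lost in replicate 2 alone. The cuticle difference, -14.3 percentage points, was -11.7 with 5 kb added (adjusted permutation p = 0.146) and -1.94 with the gene span alone, neither past the threshold. With peaks counted inside the gene span alone, the list of ribosomal proteins was the single one past the threshold. Its difference from matched lists then fell from 54.7 to 17.8 percentage points (adjusted permutation p = 0.0190).

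The remaining 13 lists did not pass. Ecdysone response genes came nearest on the higher side, with 20 of 28 (71.4% against 52.9%, raw permutation p = 0.0472, adjusted p = 0.112). They include strong peaks at nuclear receptor genes: Eip75B had 16 peaks with a top rank of 23, Eip78C had 5 with a top rank of 59 and Hr4 had 10 with a top rank of 66. ImpL2, which encodes a secreted insulin-binding protein, had 3 with a top rank of 164. On the lower side, 1 of 22 Mst genes had a peak (raw permutation p = 0.0400, adjusted p = 0.109), Mst85C, and 3 of 15 phototransduction genes (adjusted p = 0.136), norpA (top rank 44), rdgA and Rh5. The Mst list includes the Y genes Mst77Y-4, Mst77Y-7, Mst77Y-9 and Mst77Y-13. These could not have a peak, as no pooled call lay on the Y. With lists matched also on chromosome arm, the Mst difference was -17.3 percentage points (adjusted permutation p = 0.122). Among eye genes 14 of 22 had a peak, with 10 at aop, 7 at Egfr, 6 at spi and 1 at dpp, and among antennal genes 7 of 10, with 11 at hth. For the Runx family and cofactors the count was 4 of 8, lz, Bgb, Bro and the corepressor gene gro (top rank 186). The Hox list had 4 of 8 genes with a peak, with 10 peaks at Antp, muscle genes 5 of 12, neuronal genes 5 of 10 (3, 2 and 2 without replicate 1, 2 and 3), fat body genes 4 of 9 and glue and salivary gland genes 1 of 11, fkh. Without replicate 1 or 3, Mst85C, Rh5 and Bro had no peak, so the Mst count was 0 of 22. The peaks at Eip78C numbered 3 without replicate 1, those at aop 6 without replicate 2 and 5 without replicate 3, and those at Egfr 4 without replicate 2.

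**Figure D2:**
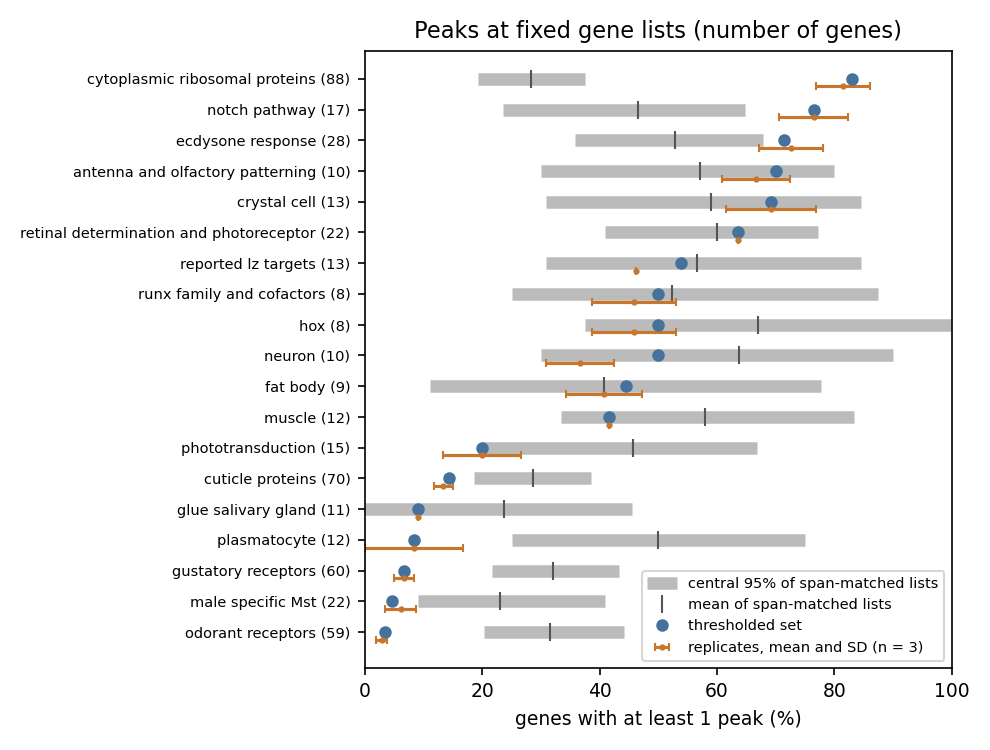
Percent of the genes of each fixed list with at least 1 thresholded peak (blue), the replicates' mean and SD (orange, n = 3) and the mean and central 95% of 10000 span-matched lists (grey). Ribosomal protein genes lie at 83.0% against 28.2%, and odorant receptor genes at 3.39% against 31.5%.

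Whether summits carry the Runx recognition sequence was asked with the consensus RACCRCA in 101-bp windows, against windows 500 bp to 1 side. The consensus was in 216 summit windows (2.68%) and 340 flank windows (4.22%), a ratio of 0.635 (95% bootstrap interval 0.539 to 0.754; exact McNemar test over 16 motifs, adjusted p = 2.37e-07) and 0.668 ± 0.0637 across replicates (SD, n = 3). Summit windows were AT-rich, with 33.7% G and C against 44.1% in flanks. Against positions of the same G and C content, the ratio was 0.780 (0.654 to 0.918, adjusted exact p = 0.0189), and 0.880 ± 0.0512 across replicates. Permuting the letters of the consensus gave ratios to flanks at or below that of the Runx consensus in 44 of 100 permutations, and in 15 of 100 against GC-matched positions. Peaks within 500 bp of a TSS had a ratio to flanks of 0.768 (adjusted exact p = 0.0745), and peaks farther away had 0.558 (adjusted exact p = 4.86e-07).

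Promoter elements were the sequences most enriched at summits. The DNA replication-related element TATCGATA was in 129 summit windows and 22 flanks, a ratio of 5.86 (adjusted exact p = 6.93e-19), and 5.86 also against GC-matched positions (adjusted exact p = 1.03e-18), above all 100 permutations of its letters there. The core promoter sequence GGTCACACT, bound by M1BP, was in 58 summit windows and 5 flanks, a ratio of 11.6, with 19.3 (7.67 to 67.0) against GC-matched positions. The GC-matched ratios across replicates were 5.65 ± 1.97 for TATCGATA and 52.3 ± 32.0 for GGTCACACT (SD, n = 3). For the thresholded set, GGTCACACT was in 0.0373% of GC-matched windows, so its ratio there rests on very few windows. For TATCGATA the ratio to flanks was 9.58 within 500 bp of a TSS and 1.40 farther away, where it did not pass (adjusted exact p = 0.577); the difference between them was not tested. Its ratio over all peaks was 3.67 without replicate 1. For GGTCACACT the ratio to flanks was 6.16 ± 1.59 across replicates and 17.5 without replicate 3. It was 23 within 500 bp of a TSS and 4 farther away (adjusted exact p = 0.0536), and 12.0 at the distant peaks with flank sides drawn anew (adjusted exact p = 0.00608), so the distant value moves with the sides drawn. The CGATAT sequence of the insulator protein BEAF-32 had a ratio of 1.65 to flanks and 1.32 to GC-matched positions (adjusted exact p = 0.000304), with 1.41 ± 0.0372 across replicates for the latter. Its ratio to flanks was 2.28 within 500 bp of a TSS and 1.16 farther away, where it did not pass (adjusted exact p = 0.219), and 11 of 100 permutations of its letters had a ratio to GC-matched positions as high. CGATAT can overlap TATCGATA, and windows holding both were not counted apart. GATA sites were in 16.6% of summit windows, 1.56 times the flanks but 1.10 times GC-matched positions, where 20 of 100 permutations of its letters had a ratio as high.

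Over all 16 motifs, 5 were more frequent at summits than in flanks and 10 less frequent, but against GC-matched positions 7 were more frequent and 1, the Runx consensus, less frequent. The GAGA sequence, the Grainyhead site and the CAGCTG E-box turned from lower (0.597, 0.720 and 0.598) to higher (1.16, 1.60 and 1.26; across replicates 1.09 ± 0.108, 1.89 ± 0.456 and 1.41 ± 0.314, SD, n = 3). Across replicates the Grainyhead ratio to flanks was 1.00 ± 0.109, so its lower value was not seen there. Permutations of the letters with a ratio to GC-matched positions as high numbered 0 of 9 for GAGA, 5 of 100 for Grainyhead and 18 of 100 for CAGCTG. The homeodomain site went from 1.68 to 0.909, which was not past the threshold. The Suppressor of Hairless, CACGTG, Zelda, Ets, ecdysone receptor core and FTZ-F1 sites were lower against flanks, and none of these 6 passed against GC-matched positions. The AP-1 site passed neither test, though it was lower than flanks within 25 bp of the summit (0.587, adjusted exact p = 0.0393) and at the 4024 strongest peaks (0.535, adjusted exact p = 0.0213). Against flanks, the Grainyhead call was lost without replicate 1, 2 or 3 (adjusted exact p = 0.232, 0.294 and 0.115), the Zelda call without replicate 1 or 2 (0.0869 and 0.113) and the Ets call without replicate 1 or 3 (0.0697 and 0.447). The Zelda call was also lost with 25 bp each side (adjusted exact p = 0.0689) and with flanks at 1000 bp (0.147). It was lost too at the 4024 strongest peaks (0.142) and at peaks over 500 bp from a TSS (0.0742). The Grainyhead call was lost in all of these settings. The Ets call was also lost with flanks at 1000 bp (0.0918) and at peaks over 500 bp from a TSS (0.249).

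**Figure D3:**
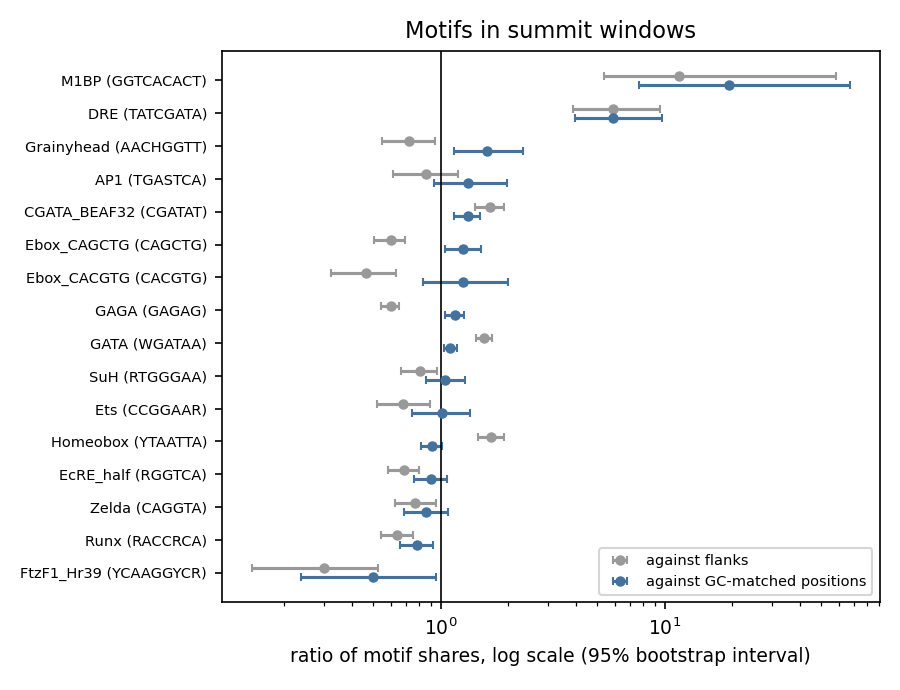
Ratio of the share of thresholded summit windows with each motif to the share of flank windows (grey) or of GC-matched positions (blue), on a log axis with 95% bootstrap intervals. TATCGATA and GGTCACACT lie far above 1 on both, and the Runx consensus lies at 0.635 and 0.780.

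By strength, the share of summits with the Runx consensus was 1.86% in the strongest 20 percent of the thresholded set and 3.54% in the weakest, a difference of -1.68 percentage points, with a mean of -1.55 ± 0.559 across replicates (SD, n = 3). In windows of 100 bp each side it was -0.928. Promoter peaks made up 49.3% of the strongest 20 percent and 39.7% of the weakest. Mean G and C content was 31.3% in the former and 35.9% in the weakest 20 percent. No test was run on these differences.

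**Figure D4:**
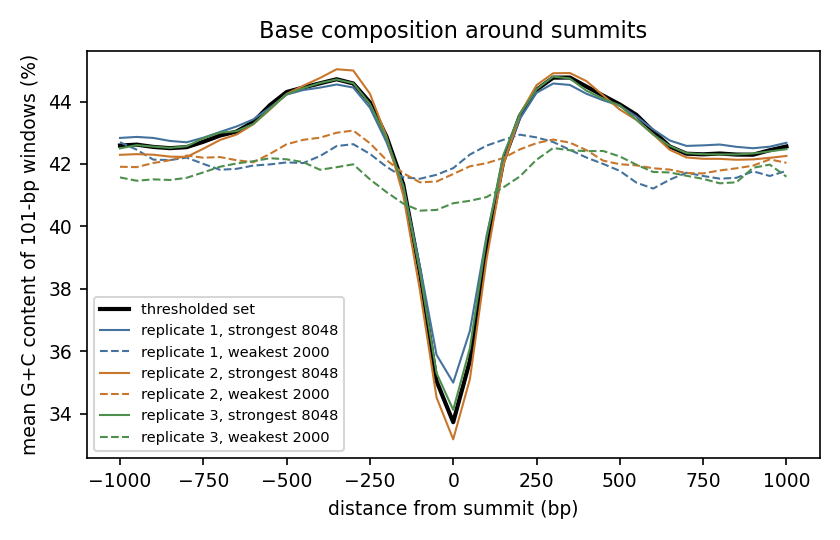
Mean G and C content of 101-bp windows by distance from the summit in bp, for the thresholded set (black), the 8048 strongest (solid) and the 2000 weakest (dashed) calls of each replicate. Content falls to 33.7% at thresholded summits and stays near its surroundings at the weakest calls.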

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

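Both results here concern calls that the report does not otherwise describe, and no explanation was tested for either. Of the 21952 pooled calls below the authors' threshold, 12 lay within 100 bp of a call among the 8048 highest of all 3 replicates. On the dm3 build, 6 thresholded peaks lay on heterochromatic or unplaced scaffolds, 2 each on 3LHet, XHet and U; the 2 on U overlap each other, so they mark 1 region.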

How the results depend on the processing

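The GC-matched positions, the permuted consensus, the single-replicate gene lists and the chromosome length between first and last call were chosen after seeing the data. The promoter excess kept its direction and its side of the threshold under all 7 alternatives, and the call of ribosomal protein genes under all 11, with differences of 17.8 to 55.5 percentage points and adjusted p from 0.00380 to 0.0190. The calls of odorant and gustatory receptors were kept under 10 of 11, that of the Notch pathway under 7, of cuticle proteins under 6 and of plasmatocytes under 5. Read depth is unknown, so its part in any of these is open, and the cause of the changes below was not tested unless given.

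Mean pairwise agreement was 60.5% at 50 bp, 80.7% at 250 bp, 80.7% with 4024 peaks per replicate and 61.8% with 2 times as many; it ranged from 71.7% to 77.1% when 1 replicate was left out. The share of thresholded peaks found in every replicate was 50.4% at 50 bp and 72.1% at 250 bp. It was 36.5% with 4024 peaks per replicate, a number that cannot hold all thresholded peaks, 84.1% with 2 times as many and 93.2% for the 4024 strongest peaks. It was 70.9% to 75.7% when 1 replicate was left out, where a peak needs fewer replicates.

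Peaks at lz numbered 4 with 5 kb added to the gene span, 1 in the 4024 strongest peaks and 2 to 3 when 1 replicate was left out. The X to autosome ratio was 1.05 on dm3, with lengths taken to the last call, and 1.11 on dm6 with lengths from first to last call. The Runx difference between the strongest and weakest 20 percent was -0.928 percentage points in windows of 100 bp each side. Ranking the thresholded peaks by the −log10 q-value gave no value, since that column is constant there.

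The Runx ratio stayed below 1 and past the threshold in the 9 alternatives with flanks as background and against GC-matched positions. Divided by the median ratio of its permutations it was 0.970 and no longer past it (p = 0.891). Against GC-matched positions these ratios changed sides of 1: GAGA 1.16, Grainyhead 1.60, Suppressor of Hairless 1.05, CAGCTG 1.26, CACGTG 1.25, AP-1 1.33, Ets 1.01 and the homeodomain site 0.909. The low GC content of summits is built into the flank comparison and removed from this one. The GC-matched positions also lie elsewhere, over 1 kb from any pooled peak, and these differences were not separated. Grainyhead was at 1.01 with flanks at 1000 bp. With windows of 25 and 100 bp each side, GGTCACACT was at 7.00 and 4.85 and TATCGATA at 10.6 and 6.35, all past the threshold.

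With the gene span alone, 1 list was higher and 0 lower. With 5 kb added, 1 was higher and 2 lower, and replicate 3 alone gave 1 higher; leaving out 1 replicate gave 1 to 2 higher. Ecdysone response genes passed without span matching and in replicate 1 alone, with an adjusted p of 0.00380 and 0.0285 (range over its alternatives 0.00380 to 0.399). Mst genes also passed without span matching, on the lower side (-33.4 percentage points, adjusted permutation p = 0.00633). The reversals below are all in lists that never passed. Differences in percentage points were 0.285 for reported lz targets and -2.5 for fat body genes with the gene span alone. Without span matching, which leaves long genes at an advantage, they were 16.0 for lz targets, 12.0 for the Runx family and for Hox genes, 3.88 for muscle and 12.3 for neuronal genes. In the 4024 strongest peaks they were -0.695 for antennal genes, 1.5 for the Runx family and 1.21 for muscle. For fat body genes the difference was -6.65 in replicate 3 alone. Leaving out 1 replicate gave -2.70 to 9.20 for eye genes, -0.895 to 11.2 for antennal genes, -5.93 to 3.84 for the Runx family and -1.14 to 3.36 for fat body genes. Of the 94 named genes, 68 had a peak, and 54 had one in the 4024 strongest peaks, 42 in the gene span alone and 73 with 5 kb added.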

Other observations

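The tests of peaks at a gene's own TSS, of permuted consensus sequences and of base composition were chosen after the results were seen; those of GC-matched positions and of distance from promoters for the Runx consensus were set out before their results were seen.

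Peaks at ribosomal protein genes sat at the TSS. Of the 73 such genes with a peak, 70 (95.9%; 95.2% ± 3.52 across replicates, SD, n = 3) had a thresholded summit within 500 bp of an own TSS, against 74.7% of span-matched genes that also had a peak (adjusted permutation p = 0.00380) and 3763 of all 5328 protein-coding genes with a peak (70.6%). None of the 10 cuticle protein genes with a peak had one so close, against 70.3% of matched genes (adjusted permutation p = 0.00380), and Cpr72Ea and Cpr72Eb share 1 peak, at -518 bp from the TSS of the latter. The single replicates put a peak within 500 bp of the TSS at 0.476% ± 0.825 of the 70 cuticle protein genes (SD, n = 3). For gustatory receptor genes the count was 0 of 4 with a peak (75.9% in matched genes, adjusted permutation p = 0.0342), 1 gene being left without replicate 1 or 3, and for odorant receptor genes 0 of 2 (adjusted permutation p = 0.312). The peak at Gr32a was at -803 bp from its TSS. Notch pathway genes had a TSS peak in 10 of 13 with a peak (76.9% against 61.9%, adjusted permutation p = 0.693), crystal cell genes in 8 of 9 (adjusted permutation p = 0.312) and genes reported to respond to lz in 3 of 7 (adjusted permutation p = 0.788).

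The Runx consensus was less frequent at summits of this Runx factor than in their flanks. The deficit was not confined to promoters, as peaks over 500 bp from a TSS had a ratio to flanks of 0.558. Those summits were AT-rich too, by -10.7 percentage points, so this ratio does not separate promoters from base composition. Matching on GC content gave a ratio of 0.780, with an interval still below 1. That does not set base composition aside, since permutations keep the letters and 15 of 100 were as scarce or scarcer there. Against flanks 44 of 100 permutations were, and their median ratio was 0.655. The letters of the consensus in any order are a candidate explanation. The deficit may then say nothing about the Runx sequence in particular, and no enrichment of it was seen either. No biological explanation was tested, as there is 1 group, and binding through partner proteins stays open. No sample without the tagged protein was analysed here, so peaks that do not depend on lz could not be told apart.

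Summit windows were AT-rich, by -10.4 percentage points of G and C relative to their flanks (SE 0.149 across peaks). AT-rich promoter DNA alone is argued against by peaks over 500 bp from a TSS, where the difference was -10.7. A preference of the whole libraries for AT-rich DNA stays open. The difference at the 2000 weakest calls of each replicate was at most 0.119 of that at the 2000 strongest. However, calls are ranked by signal, which such a preference would itself raise at AT-rich sites. The lists also hold background regions, so the weakest calls need not be peaks. A bias of the control stays open too, and no biological explanation was tested.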
